A study of Mus musculus with 24 samples.

How the data were processed

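RNA was sequenced from 24 libraries of progenitor B cells sorted by flow cytometry from the bone marrow of C57BL/6J mice. Per the labels, 3 populations were taken. P1 was positive for B220, CD19, CD93 and CD43 and negative for CD25, P2 was positive for all 5 markers, and P3 had lost CD43 and kept CD25. Each population was taken from mice with floxed Erg alleles alone, called WT in the labels, and from mice that also carried the CD2iCre recombinase, called KO. There were 4 libraries per population and genotype, which the series text calls biological replicates without naming animals. Groups and replicate numbers were read from the library titles. For the P3 libraries the population field of the labels names P2 while listing the markers of P3, and the title was used.

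Per the labels, RNA was extracted with a Qiagen micro kit, amplified to cDNA and made into libraries with NuGEN Ovation kits and sequenced on an Illumina NextSeq. The submitters' processing notes name STAR, Salmon, FastQC, MultiQC and limma, with no versions, roles or order, and the genome build mm10. The annotation release and any use of strand in counting are not given in the sources used here, so reads of a gene and of an overlapping or antisense gene were not separated. Per the file headers, the authors deposited an estimated count per gene and library that was called a raw read count, and the values were not whole numbers. The authors also deposited log2 CPM values per library, normalised by a method that the sources used here do not give. Per the file headers, the deposited tables further held the authors' own limma comparison within each population, as a log2 fold change with its confidence limits, a p-value and an adjusted p-value. Genes had been filtered separately per population, leaving 17711 genes in P1, 17759 in P2 and 18588 in P3, with 16148 present in all 3 tables. Symbols were missing for 345, 339 and 374 of these, and 18, 20 and 19 symbols had become calendar dates. The dated ones were replaced by the symbol of the same gene identifier in a reference table, which filled 18, 20 and 19. Coordinates were taken from GENCODE M21 (build GRCm38, the same assembly as mm10), in which 19619 of the 20058 gene identifiers were found. No per-library column was left unmapped.

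The deposited estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries were scaled by TMM, and the quasi-likelihood F test with robust fitting compared KO with WT within each population. Benjamini-Hochberg adjustment was applied over all genes tested, and a gene was called at an adjusted p under 0.05 in a two-sided test. Fold changes are given as log2 of KO over WT with their standard error (SE). CPM values were computed on the TMM-scaled library sizes. Because the tables held raw counts for the genes common to all 3 populations, the difference of the KO effect between populations and the stage differences among WT libraries were fitted in the same way over these common genes. The 29 gene lists and segment families, 18 given as genes and 11 as symbol patterns, were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists within a population. Each list was tested again with an estimated correlation. Igh V segments were summarised per library as a median log2 CPM and as a summed CPM, and genotypes were compared by an exact two-sided permutation test over the 70 assignments of 8 libraries, for which the smallest possible p is 0.0286. Distal segments were those of the Ighv1 and Ighv8 families, which lie farthest from the D and J segments, and proximal segments were those of the Ighv5 and Ighv2 families.

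The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined, apart from the alternatives given below as added. Named genes were Erg, then per population the 10 genes with the largest rise and the 10 with the largest fall among called genes in which every KO library lay beyond every WT library, leaving out immunoglobulin and T cell receptor segments, predicted genes and Rik clones. To these were added the 3 members of each list with the smallest p and a fixed set of 21 regulators and markers of B-cell development. A fold against a group with 0 counts was set against a floor of 3 counts over that group and is a lower bound. With 1 to 3 counts the ratio of totals is given with its exact 95% interval. Reads came from amplified cDNA without molecular identifiers, so these intervals and floors cover counting error only. Immunoglobulin V segments are a multigene family of close copies, and how reads were divided among them is not known.

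Total counts per library ran from 9.36M to 18.7M. Libraries of a group differed far beyond sampling noise, with a chi-square per degree of freedom of 24.1 to 203 for pairs within a group, and none was counted as a duplicate. The test was checked on simulated counts with the real means and library sizes, in which 200 genes were changed. In the simulation of P1 (15295 genes) it recovered 9% of genes changed by 2-fold and 69% of those changed by 4-fold. The corresponding shares were 24% and 83% in P2 (15576 genes) and 16% and 75% in P3 (16152 genes). Unchanged genes made up 2.38%, 5.3% and 1.96% of the calls, so the design mostly registers changes well above 2-fold.

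Alternatives covered the replicate number as a block, leaving out each library, DESeq2 1.42.0 with its Wald test, DESeq2 size factors, no expression filter, edgeR without robust fitting, voom with weights per library, all 24 libraries in 1 fit, a minimum absolute log2 fold change of 1, and the deposited comparison of the authors. Fits that left out libraries or added a block or covariate used the genes of the main comparison of that population. Added after seeing the data were limma on the authors' log2 CPM, the level of the predicted gene Gm10800 as a covariate, and fits without the libraries in which Gm10800 took over 0.3% of counts. No library was left out of the main comparisons. Other splits of the libraries were refitted to see how often they gave as many calls. A stage score placed libraries between WT profiles of their population (0) and a neighbouring one (1) on log2 values. The axis used 2 of the 4 own WT libraries, with scores averaged over the 6 choices. WT scores averaged 0.267 (P1), 0.228 (P2) and 0.468 (P3), so 0 is no baseline.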

Results

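Transcript levels were measured by RNA sequencing in progenitor B cells of 3 consecutive sorted populations, P1, P2 and P3, from mice with floxed Erg alleles with or without the CD2iCre recombinase. The 24 libraries formed 6 groups of 4. Erg encodes an ETS-family transcription factor, and the series title ties it to early B-cell development and to the joining of Igh V segments to DJ segments. Total counts per library ran from 9.36M to 13.9M in P1 KO and from 12M to 18.7M in P1 WT. They ran from 11.8M to 15.2M in P2 KO, from 10.6M to 17.1M in P2 WT, from 14M to 16.9M in P3 KO and from 11.2M to 14.5M in P3 WT. Reads from a pair of mitochondrial ribosomal RNA genes, mt-Rnr1 and mt-Rnr2, made up 12.6% to 25.2% of the counts of a library.

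**Figure D1:**
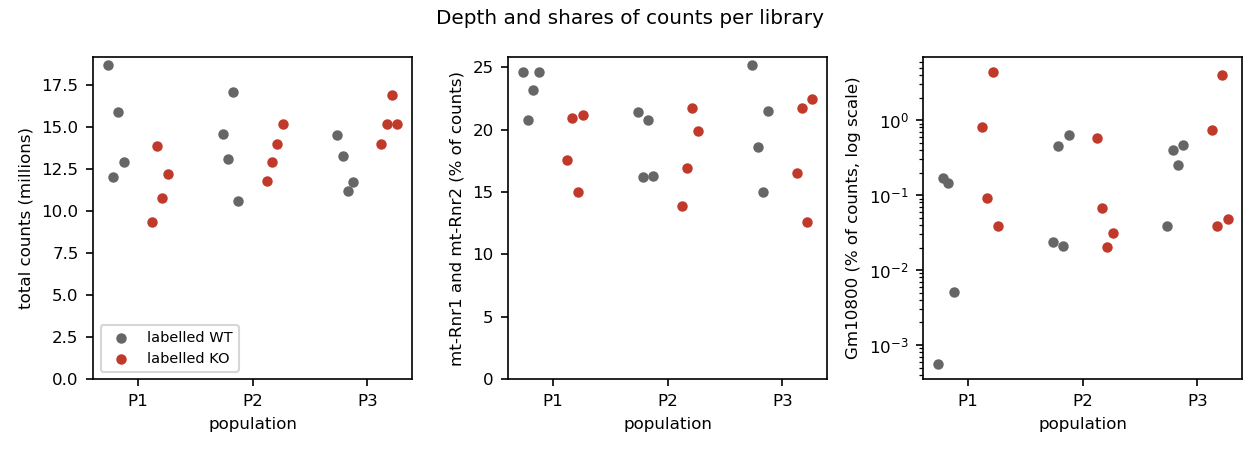
Total counts, percent of counts on mt-Rnr1 and mt-Rnr2, and percent on the predicted gene Gm10800 (log axis) for each of the 24 libraries, grouped by population and genotype. Gm10800 reached 4.45% in P1 KO replicate 3 and 4.07% in P3 KO replicate 3.

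Erg (ENSMUSG00000040732, mm10 chromosome 16, 95359169 to 95586593, minus strand) was detected in every library. In P1 it was measured at 587, 436, 576 and 393 CPM in the 4 libraries labelled KO and at 596, 572, 612 and 880 CPM in the WT libraries, with a log2 fold change of -0.42 (SE 0.19, edgeR adjusted p = 0.383). In P2 it was measured at 426, 370, 271 and 307 CPM in the libraries labelled KO against 45.3, 49.3, 44.4 and 43.3 CPM in WT, a log2 fold change of 2.91 (SE 0.17, edgeR adjusted p = 4.12e-05). In P3 the values were 157, 130, 136 and 152 CPM against 12.5, 16.5, 6.68 and 20.6 CPM, a log2 fold change of 3.35 (SE 0.31, edgeR adjusted p = 0.00344). Total Erg counts therefore did not fall in any population past the test, and in P2 and P3 they rose in the libraries labelled KO. The authors' deposited table gave log2 fold changes of -0.42, 2.90 and 3.54 for the same contrasts. Which exons are floxed is not given in the labels, and reads were summed over the gene, so a transcript lacking some exons would still be counted. These counts neither show nor exclude the deletion, and every direction given here is that of libraries labelled KO against libraries labelled WT.

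**Figure D2:**
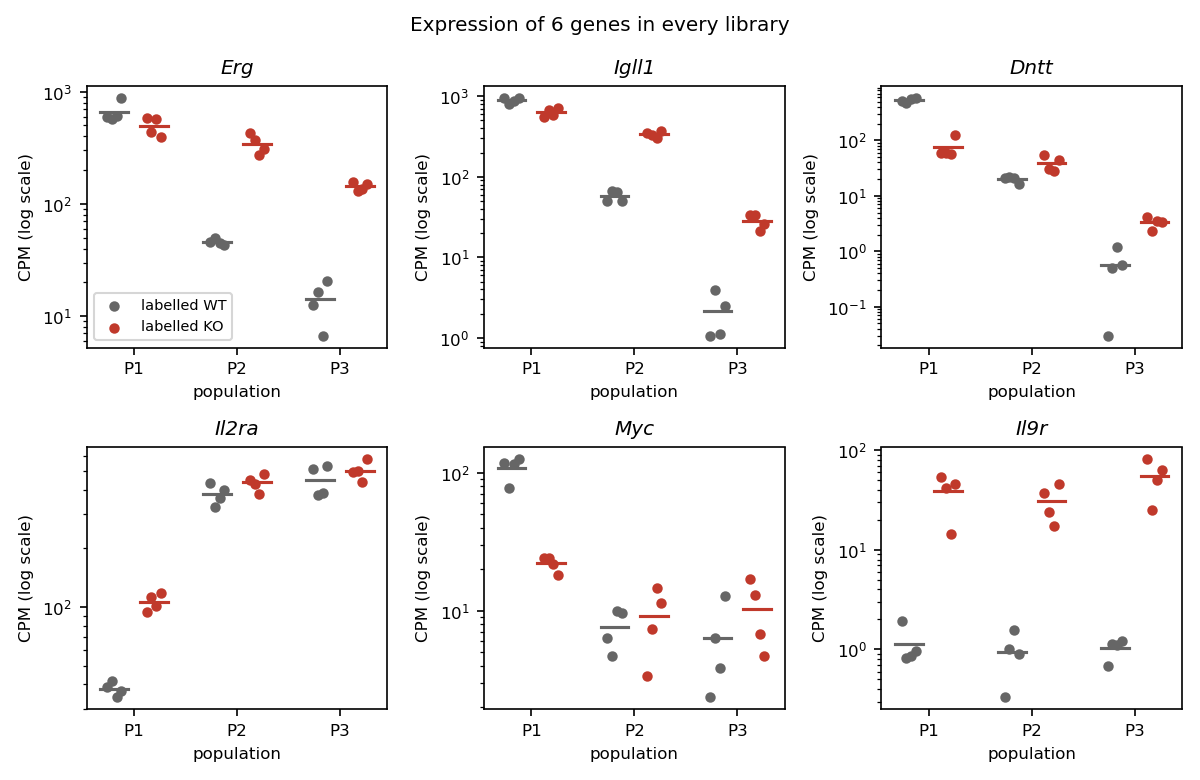
CPM (log axis) of Erg, Igll1, Dntt, Il2ra, Myc and Il9r in every library of the 6 groups, with bars at group means, and with a library at 0 counts drawn at the bottom of the axis. Erg lay at 271 to 426 CPM in P2 KO libraries and at 43.3 to 49.3 CPM in P2 WT libraries.

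The comparison in P1, the earliest population, asked which transcripts differed with genotype before CD25 appears. In P1 libraries labelled KO, Dntt, which encodes the polymerase that adds untemplated nucleotides at V(D)J joints, fell by 2.81 on the log2 scale (SE 0.27, edgeR adjusted p = 0.000599), from 531 ± 48.3 to 75.9 ± 33.7 CPM (mean ± SD, n = 4). Myc, a driver of growth in cycling progenitors, fell by 2.31 (from 109 ± 21.2 to 22 ± 2.91 CPM), and Lef1, a transcription factor of pro-B cells, fell by 1.67 (from 807 ± 162 to 254 ± 12.5 CPM), each with an edgeR adjusted p of 0.000599. Il2ra, which encodes CD25, rose by 1.49 (SE 0.19, edgeR adjusted p = 0.00234), from 38 ± 3.03 to 106 ± 10.7 CPM, although P1 was sorted as CD25-negative. Cd74, the invariant chain of MHC class II, rose by 2.37 (from 72.4 ± 29.3 to 375 ± 163 CPM), with 618 CPM in P1 KO replicate 4 and 272 to 315 CPM in the other 3. H2-Aa rose by 1.95 and Polm, a polymerase of end joining, by 2.29. Syk, a kinase below the pre-B-cell receptor, rose by 1.03, Cd38 by 1.68, Klf2, a factor of quiescent lymphocytes, by 2.22, and Ly6d from 14.3 ± 2.05 to 114.5 ± 93.4 CPM, with 253 CPM in P1 KO replicate 4 and 57.5 to 88.8 CPM in the other 3. Ccnd2, a cyclin under IL-7 control, fell by 1.35. These 12 genes were called in each of the 8 fits that left out 1 library.

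In P1, 290 of 15773 genes were called by edgeR with Benjamini-Hochberg adjustment, of which 133 rose and 157 fell in libraries labelled KO. The KO and WT libraries did not overlap in 1408 genes, 8.93% of those tested, where chance gives 2.86%. Called genes included 11 immunoglobulin segments of 88 tested and 16 predicted or unnamed genes. The count was 132 without P1 KO replicate 1, 131 without P1 KO replicate 2, 169 without P1 WT replicate 3 and 161 without P1 WT replicate 4. With the level of Gm10800 as a covariate it was 139, and without the P1 libraries in which Gm10800 took over 0.3% of counts it was 80, with 2 KO and 4 WT libraries left. With the replicate number as a block 150 genes were called. DESeq2's Wald test called 868 genes, and a fit to all 24 libraries called 715. The authors' deposited table held 251 genes at the same threshold, and 223 were common to both.

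Among the largest changes in P1, Mmrn1, which encodes a multimerin of platelets and endothelium, fell by 7.73 (SE 0.61, edgeR adjusted p = 0.00013), from 77.5 ± 9.76 to 0.374 ± 0.332 CPM. The sodium-channel subunit gene Scn4b fell by 5.64, the homeobox gene Dlx1 by 5.56, Zfp365 by 6.13 and the progesterone receptor gene Pgr by 5.35. Acy3 fell by 5.22, a call kept in 4 of the 8 fits without 1 library. Bok, a BCL2-family gene, had 1 count over the KO libraries, and its WT to KO ratio was 274 (95% interval 48.9 to 10860). Afap1l1 with 3 KO counts had a ratio of 49.9 (16.8 to 244), Ap3s1-ps1 with 1 count had 62.2 (10.8 to 2489), and Ccdc33 with 3 counts had 36 (12.1 to 177), and in fits without 1 library the call of Ap3s1-ps1 was kept in 0 of 8 and that of Ccdc33 in 1. The rises were led by Pmepa1, an inhibitor of TGF-beta signalling, with 688 counts over the KO libraries and 0 over WT, at least 310-fold higher. L3mbtl1 was at least 95.4-fold and Serpinh1 at least 35-fold higher (a call kept in 6 of these 8 fits). The ratio was 703 (126 to 27830) for the receptor gene Gpr25, 132 (23.2 to 5264) for Slc27a3, 86.3 (15 to 3459) for Thbs4 and 73.6 (19.9 to 615) for Etnk2, with 1, 1, 1 and 2 WT counts, all in P1 WT replicate 3, and the calls of Thbs4 and Etnk2 were kept in 6 and 5 of these fits. The renin gene Ren1 rose by 5.66, the neutrophil gene Cd177 by 5.72 (a call kept in 2 of the 8 fits without 1 library) and Kcnj15 by 5.76 (116 ± 59.1 against 2.1 ± 2.58 CPM, with 5.95 CPM in P1 WT replicate 3 and 0.526 to 1.12 CPM in the other 3). Intervals and floors cover counting error only, and fitted fold changes of genes with 0 to 3 counts in a group are no bounds.

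Surrogate light chain and recombinase genes were not called in P1. Igll1 was at 635 ± 75.7 CPM in KO and 897 ± 70.2 CPM in WT (edgeR adjusted p = 0.127), Vpreb1 at 157 ± 13.5 and 281 ± 71.4 CPM (0.0576), and Vpreb2 at 2.05 ± 1.1 and 6.21 ± 2.97 CPM (0.225). Rag1 was at 1010 ± 216 and 829 ± 154 CPM (0.574) and Rag2 at 293 ± 79 and 425 ± 48 CPM (0.261). The lineage regulators Ebf1 (957 ± 166 and 1649 ± 350 CPM, 0.0615), Pax5 (261 ± 48.7 and 187 ± 43.7 CPM, 0.341) and Ikzf1 (1067 ± 172 and 688 ± 97.5 CPM, 0.0841) and the early receptor gene Kit (17.4 ± 7.68 and 65.9 ± 42.8 CPM, 0.0867) also missed the threshold. The transcripts of the other fixed regulators and sort markers, Il7r, Cd19, Cd93, Spn, Ptprc, Ets1, Fli1, Ighm and Igkc, had edgeR adjusted p-values from 0.104 to 0.982.

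Gene lists in P1 were led by the Igh V segments, which join to DJ segments to form the heavy-chain gene. Of 39 tested, 4 fell and 0 rose, 13 fell when adjusted over the list alone, and camera gave an adjusted p of 3.8e-16 (adjusted p = 0.0296 with an estimated correlation). Of 16 distal Igh V segments 3 fell, 8 when adjusted over the list alone, with a camera adjusted p of 1e-14 (adjusted p = 0.0124 with an estimated correlation). Ighv1-58 was at least 145-fold, Ighv1-75 at least 41.4-fold and Ighv1-74 at least 19.5-fold lower, each with 0 counts over the KO libraries, and the call of Ighv1-74 was kept in 2 of the 8 fits without 1 library. MHC class II and later B-cell genes had 3 of 16 members higher (9 adjusted over the list alone), a median log2 fold change of 1.22 and a camera adjusted p of 1.24e-07 (adjusted p = 0.0904 with an estimated correlation). Light-chain segments lay higher. For Igl V, J and C segments 3 of 4 rose (3 adjusted over the list alone, camera adjusted p = 2.62e-05, and adjusted p = 0.143 with an estimated correlation). Of these Iglv1, which rose by 3.35, kept its call in all 8 fits without 1 library, Iglc2 in 1 and Iglv3 in 0. For Igk V segments 2 of 29 rose (3 adjusted over the list alone, camera adjusted p = 0.000578, and adjusted p = 0.276 with an estimated correlation), Igkv1-135 by 3.13 and Igkv4-78 at least 31.4-fold, with calls kept in 8 and 6 of these fits. For Igk J segments 0 of 4 rose (2 adjusted over the list alone, camera adjusted p = 0.00116, and adjusted p = 0.168 with an estimated correlation). Without P1 KO replicate 4 Igk V segments lost the call (camera adjusted p = 0.055).

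Camera called 5 further lists in P1. Myeloid markers had 1 of 11 members higher, the granule gene Ltf at 17.4 ± 9.96 against 4.09 ± 1.51 CPM, and 6 adjusted over the list alone (median log2 fold change 1.65, camera adjusted p = 0.000336, and adjusted p = 0.44 with an estimated correlation). Plasmacytoid dendritic cell markers had only Ly6d called of 8 and 1 adjusted over the list alone (camera adjusted p = 0.0115, and adjusted p = 0.143 with an estimated correlation). Cell-cycle genes had 0 of 29 called and 0 adjusted over the list alone (median -0.28, camera adjusted p = 0.000424, and adjusted p = 0.519 with an estimated correlation). The cytosolic ribosomal protein genes had 0 of 77 and 0 adjusted over the list alone (median -0.41, camera adjusted p = 5.12e-11, and adjusted p = 0.519 with an estimated correlation). Immediate early genes had 2 of 12 higher, Fosb and Btg2, with 6 up and 2 down adjusted over the list alone (camera adjusted p = 0.0466, and adjusted p = 0.519 with an estimated correlation). In fits without 1 library the calls of Fosb, Btg2 and Ltf were kept in 2, 1 and 0 of 8, and the call of immediate early genes was lost without P1 KO replicate 1 (0.0587), KO replicate 2 (0.11), KO replicate 4 (0.0939), WT replicate 1 (0.0864), WT replicate 2 (0.136) or WT replicate 3 (0.15) and against a background without immunoglobulin segments (0.0602). Plasmacytoid dendritic cell markers lost theirs without P1 WT replicate 4 (0.0557). Without the libraries rich in Gm10800 the camera adjusted p was 0.12 for cell-cycle genes and 0.157 for ribosomal protein genes, while over the alternatives with the preset correlation these lay from 0.000115 to 0.12 and from 5.59e-27 to 0.157.

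Camera did not call the other 18 lists in P1. Adjusted p-values were 0.0992 for proximal Igh V segments, 0.112 for early progenitor genes, in which Mycn alone rose by 4.33, and 0.303 for erythroid markers. They were 0.609 for interferon response genes and for NK and innate lymphoid markers, and 0.626 for Igh locus contraction genes and Igh constant regions. For T cell markers, adhesion genes, pre-B-cell receptor signalling and Igh D and J segments they were 0.713, with Itga4, an integrin of adhesion to stroma, that fell by 0.76 (a call kept in 7 of the 8 fits without 1 library). For V(D)J recombination genes it was 0.827, and for IL-7 and STAT5 signalling, p53 targets, mitochondrially encoded genes and replication-dependent histones 0.842. B-lineage transcription factors had 0.886 and plasma cell markers 0.957. The median and the test differed in sign for IL-7 and STAT5 signalling (median 0.21, test down), p53 targets (median -0.02, mean 0.12, test up) and mitochondrially encoded genes (median 0.37, test down), and the median and mean differed for Igh D and J segments (-0.45 and 0.02). Calls were gained by histones without P1 KO replicate 1 (0.0206), early progenitor genes without KO replicate 2 (0.0342), erythroid markers without KO replicate 3 (0.0154) and proximal Igh V segments without KO replicate 4 (0.0169). With the Gm10800 covariate and without the libraries rich in it they were gained by histones (4.2e-06 and 3.6e-06) and mitochondrially encoded genes (0.0465 and 0.000338), and with the covariate by erythroid markers (0.0273). Socs1, a suppressor of cytokine signalling, had 2 WT counts and a KO to WT ratio of 63.5 (95% interval 17.1 to 531), and its call was kept in 7 of these fits.

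**Figure D3:**
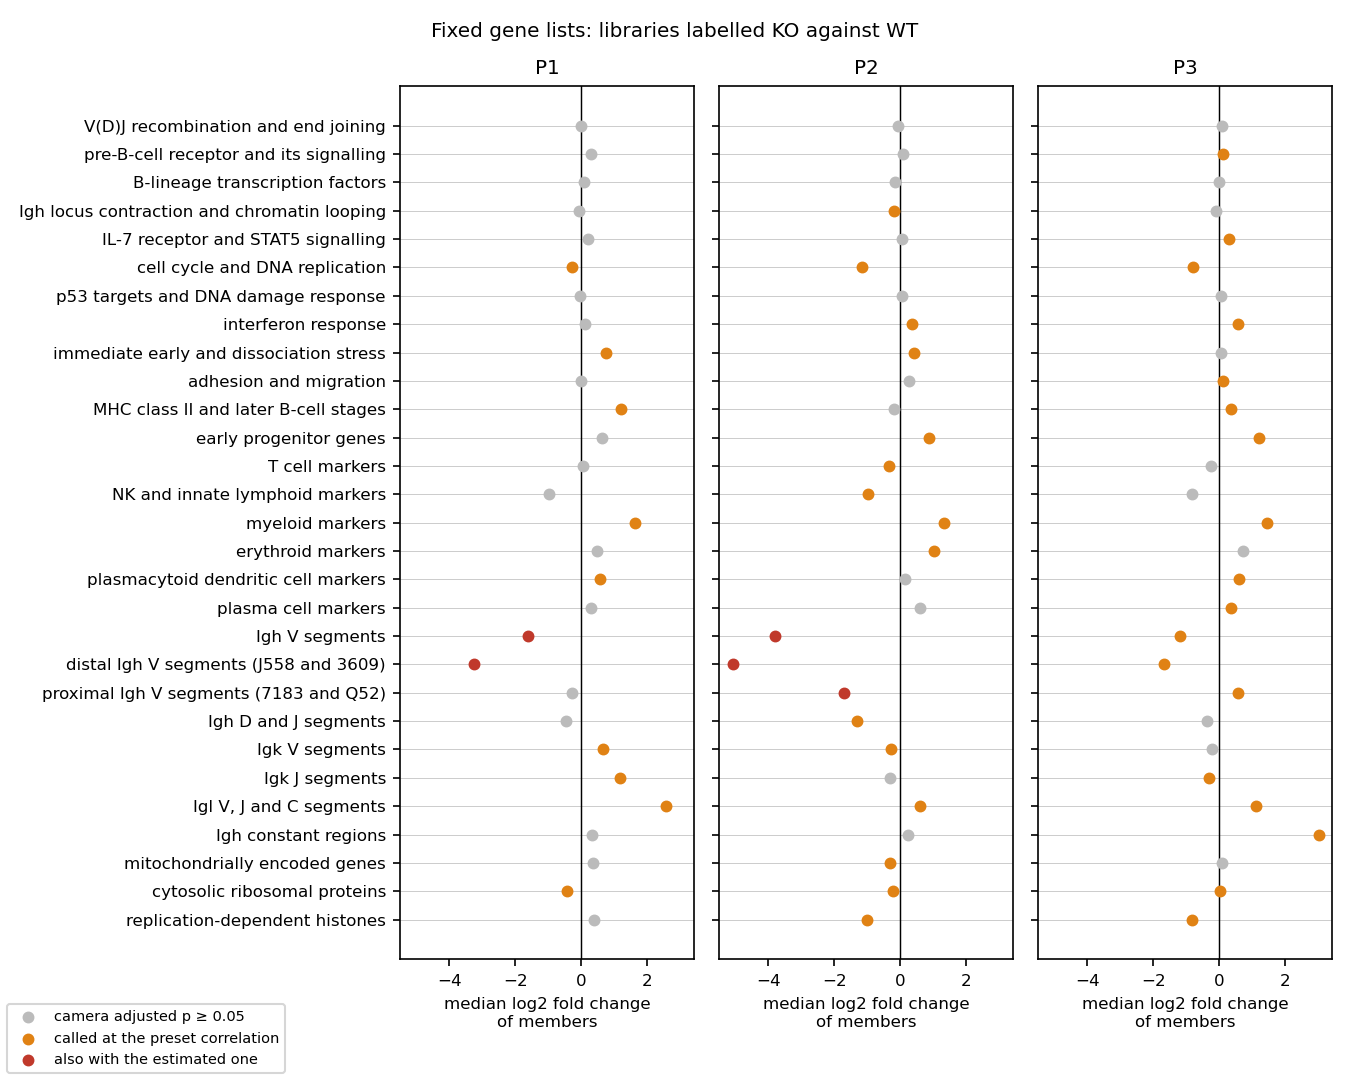
Median log2 fold change (KO over WT) of each of the 29 lists in P1, P2 and P3, coloured by whether camera called the list with the preset correlation and also with an estimated correlation. Members with 0 counts in a group enter at their bound, and distal Igh V segments had medians of -3.26, -5.08 and -1.68.

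The comparison in P2, where CD43 and CD25 are both on the surface, asked which transcripts differed with genotype as cells pass the pre-B-cell receptor stage. Igll1 and Vpreb1, which encode the surrogate light chain of the pre-B-cell receptor, rose in libraries labelled KO. Igll1 rose by 2.54 on the log2 scale (SE 0.16, edgeR adjusted p = 4.12e-05), from 57.8 ± 8.75 to 336 ± 27.7 CPM, and Vpreb1 by 2.25 (SE 0.24, edgeR adjusted p = 0.0013), from 25.1 ± 8.63 to 120 ± 14.1 CPM. Il9r, a cytokine receptor gene, rose by 5.01 (SE 0.48, edgeR adjusted p = 0.000615), from 0.948 ± 0.5 to 31.1 ± 12.9 CPM. Top2a, a topoisomerase of dividing cells, fell by 1.07 (SE 0.15, edgeR adjusted p = 0.00478, 980 ± 93.4 to 466 ± 74.1 CPM), Cdc20 by 1.54 and Cenpe by 1.43. Hmgb2, a cofactor of the recombinase, fell by 1.13. These 7 genes were called in each of the 8 fits without 1 library, as was Erg.

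In P2, 273 of 15940 genes were called by edgeR with Benjamini-Hochberg adjustment, of which 103 rose and 170 fell. The groups did not overlap in 1259 genes, 7.9% against 2.86% by chance. Of the called genes 49 were immunoglobulin segments, 48 lower and 1 higher, of 170 tested, and 10 were predicted or unnamed. The count was 170 without P2 KO replicate 4 and 138 without P2 WT replicate 3. It was 433 with the level of Gm10800 as a covariate and 97 without the libraries rich in Gm10800, which left 3 KO and 2 WT libraries. DESeq2's Wald test called 721 genes. The authors' deposited table held 256, with 221 common to both.

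The largest rises in P2 after these were Kcnj15, an inward-rectifier potassium channel gene, by 6.53 (from 0.72 ± 0.969 to 65.7 ± 25 CPM), the protease gene Htra3 by 4.49, Myo18b by 4.35, Prmt2 by 4.31 and Pmepa1 by 3.74. The Notch target Heyl rose by 3.63, Sytl2 by 3.58, Hoxa6 by 3.28 and Zfp879 by 3.25. The largest falls were Fsbp, with 0 counts over the KO libraries and at least 60.3-fold lower, and the alarmin gene Il33, with 3 counts and a WT to KO ratio of 42.5 (95% interval 14.2 to 209). Serpinb8 fell by 3.51, Tmem132e by 3.43, Nrgn by 3.27, Cd3g by 3.82, Inppl1 by 2.33 and Rragd by 2.30. Tnfrsf19, a receptor of the TNF family, fell by 2.56 (from 79.9 ± 21.2 to 13.5 ± 1.73 CPM) and the carboxypeptidase gene Cpm by 1.99 (from 301 ± 28.5 to 75.9 ± 7.43 CPM). In fits without 1 library Kcnj15, Htra3, Myo18b, Heyl, Fsbp, Inppl1, Rragd, Tnfrsf19 and Cpm passed in all 8. Prmt2 passed in 3, Zfp879 in 4, Il33, Serpinb8 and Nrgn in 2, Cd3g in 0, Tmem132e in 6, and Hoxa6, Pmepa1 and Sytl2 in 7.

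The regulators fixed in advance were mostly not called in P2. Dntt was at 38.9 ± 12.1 CPM in KO and 19.7 ± 2.35 CPM in WT (edgeR adjusted p = 0.0783), Rag1 at 1338 ± 200 and 929 ± 236 CPM (0.274), Rag2 at 232 ± 38.4 and 197 ± 33.5 CPM (0.699), and Vpreb2 at 1.32 ± 0.675 and 0.177 ± 0.265 CPM (0.21). Ighm, the heavy-chain constant region, was at 2376 ± 470 and 3177 ± 654 CPM (0.418), and Il2ra at 437 ± 42.9 and 381 ± 45.9 CPM (0.689).

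Igh V segments fell as a family in P2. Of 76 tested, 44 fell and 0 rose, 60 fell when adjusted over the list alone, and camera gave an adjusted p of 1.41e-84 (adjusted p = 0.00265 with an estimated correlation). Distal segments had 28 of 39 lower (33 adjusted over the list alone, camera adjusted p = 8.63e-69, and adjusted p = 0.00265 with an estimated correlation). Proximal segments had 6 of 16 lower (9 adjusted over the list alone, camera adjusted p = 1.89e-16, and adjusted p = 0.0247 with an estimated correlation). Ighv1-81 went from 61.5 ± 21.4 to 0.461 ± 0.391 CPM (edgeR adjusted p = 0.00017), while Ighv10-3 fell by 6.58 and Ighv1-19 by 4.41. Ighv1-78 had 1 KO count and a WT to KO ratio of 335 (95% interval 59.7 to 13260), and proximal Ighv5-15 had 3 KO counts and a ratio of 62 (20.9 to 304). Igh D and J segments had 2 of 3 lower, Ighj3 by 1.53 and Ighj4 by 1.30, each kept in 7 of the 8 fits without 1 library (3 adjusted over the list alone, camera adjusted p = 6.21e-05, and adjusted p = 0.174 with an estimated correlation). Igk V segments had 1 higher, Igkv4-78, and 2 lower, Igkv6-15 and Igkv6-32, of 72, with calls kept in 0 fits without 1 library for Igkv4-78 and in 2 for Igkv6-32 (2 up and 7 down adjusted over the list alone, camera adjusted p = 0.000945, and adjusted p = 0.557 with an estimated correlation).

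Cell-cycle genes, which mark the proliferative burst of large pre-B cells, had 13 of 29 lower in P2 and 23 adjusted over the list alone (median log2 fold change -1.14, camera adjusted p = 4.4e-22, and adjusted p = 0.169 with an estimated correlation). Replication-dependent histones had 1 of 59 lower, Hist1h2br (kept in 1 of the 8 fits without 1 library), and 30 adjusted over the list alone (camera adjusted p = 1.27e-21, and adjusted p = 0.253 with an estimated correlation). Early progenitor genes had 1 of 11 higher, the homeobox gene Meis1 by 1.57, and 2 adjusted over the list alone (median 0.89, camera adjusted p = 0.00411, and adjusted p = 0.137 with an estimated correlation). Interferon response genes had 2 of 17 higher, Oas1a by 2.14 and Ifi44 by 2.36 (kept in 7 of these fits), and 3 adjusted over the list alone (camera adjusted p = 0.0185, and adjusted p = 0.395 with an estimated correlation). T cell markers had 1 of 14 lower, Cd3g with 4 KO counts, and 1 adjusted over the list alone (camera adjusted p = 0.0455, and adjusted p = 0.413 with an estimated correlation). The call of interferon genes was lost without P2 KO replicate 3 (0.0751) or WT replicate 2 (0.0629). That of T cell markers was lost without KO replicate 1 (0.0659), KO replicate 2 (0.127), KO replicate 4 (0.0886), WT replicate 2 (0.05) or WT replicate 4 (0.196), against a background without immunoglobulin segments (0.0724) and with the Gm10800 covariate (0.0784). Without the libraries rich in Gm10800 the values were 0.0657 and 0.275.

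Of the remaining lists called in P2, none of the members passed over all genes. Myeloid markers had a positive log2 fold change in 16 of 16 members (median 1.34, camera adjusted p = 0.017, and adjusted p = 0.558 with an estimated correlation), with 0 adjusted over the list alone. The levels of the myeloid genes Mpo (281 against 123.2 CPM), Ngp (932 against 292 CPM) and S100a9 (521 against 189 CPM) had edgeR adjusted p-values of 0.805, 0.607 and 0.622. Immediate early genes, erythroid markers and Igl segments lay higher with camera adjusted p-values of 0.0329, 0.0185 and 0.0185 and 0, 0 and 1 members adjusted over the list alone (adjusted p = 0.441, 0.302 and 0.441 with an estimated correlation). Ribosomal protein genes, Igh locus contraction genes, NK and innate lymphoid markers and mitochondrially encoded genes lay lower with camera adjusted p-values of 3.91e-05, 0.0185, 0.0185 and 0.0187 and 0, 1, 0 and 0 members adjusted over the list alone (adjusted p = 0.558, 0.558, 0.253 and 0.542 with an estimated correlation). Without P2 WT replicate 2 camera called 11 lists instead of 18, 1 of them higher instead of 6, and without P2 KO replicate 3 it called 3 higher. Calls were lost for myeloid markers without KO replicate 3 (0.343), KO replicate 4 (0.135) or WT replicate 2 (0.135), for erythroid markers without KO replicate 3 (0.0751), WT replicate 2 (0.05) or WT replicate 3 (0.0597), and for Igl segments without KO replicate 4 (0.0587), WT replicate 2 (0.0831) or WT replicate 4 (0.051). They were lost for immediate early genes without KO replicate 2 (0.159), WT replicate 2 (0.132) or WT replicate 4 (0.126), and for NK and innate lymphoid markers without KO replicate 2 (0.0691). Mitochondrially encoded genes lost theirs without KO replicate 2 (0.125), KO replicate 3 (0.0804), WT replicate 2 (0.05) or WT replicate 4 (0.197), and Igh locus contraction genes without KO replicate 1 (0.0856), KO replicate 3 (0.0751), WT replicate 1 (0.103) or WT replicate 3 (0.0816). With the Gm10800 covariate myeloid markers (0.0569) and immediate early genes (0.0857) lost the call. Without the libraries rich in Gm10800 it was lost by immediate early genes (0.626), Igl segments (0.241), mitochondrially encoded genes (0.089) and erythroid markers (0.0836). Camera adjusted p-values were 0.195 for p53 targets, 0.224 for MHC class II and later B-cell genes, 0.245 for adhesion genes and 0.247 for pre-B-cell receptor signalling. They were 0.257 for B-lineage transcription factors, plasmacytoid dendritic cell markers and Igk J segments, 0.335 for IL-7 and STAT5 signalling, 0.446 for V(D)J recombination genes, 0.873 for Igh constant regions and 0.968 for plasma cell markers. B-lineage transcription factors gained a call without WT replicate 4 (0.0288) and without the libraries rich in Gm10800 (0.00177), as did MHC class II genes without the latter (0.029). Members of these lists that passed on their own were Igll1 and Vpreb1, higher, and Hmgb2, lower, all given above. Also lower were Blk, which fell by 1.02, Fcer2a by 1.39 and the plasma cell gene Sdc1 by 1.30, with calls kept in 6, 1 and 1 of the 8 fits without 1 library.

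The comparison in P3, which had lost CD43, asked which transcripts differed with genotype in small pre-B cells. Il9r rose by 5.72 on the log2 scale (SE 0.42, edgeR adjusted p = 0.000713), from 1.03 ± 0.236 to 54.8 ± 23.6 CPM, in libraries labelled KO. Igll1, which is normally shut off after the pre-B-cell receptor stage, rose by 3.72 (SE 0.45, edgeR adjusted p = 0.0119), from 2.16 ± 1.37 to 28.5 ± 6.11 CPM. The serine protease inhibitor gene Serpina3g rose by 2.59 (SE 0.29, edgeR adjusted p = 0.00747), from 4.53 ± 1.26 to 27.3 ± 5.38 CPM. These 3 and Erg were the named genes of P3 called in each of the 8 fits without 1 library.

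In P3, 43 of 16823 genes were called by edgeR with Benjamini-Hochberg adjustment, 33 higher and 10 lower, with 1272 genes at an unadjusted p under 0.05. The groups did not overlap in 862 genes, 5.12% against 2.86% by chance. The count was 16 without P3 KO replicate 1, 10 without KO replicate 2, 20 without KO replicate 3, 9 without KO replicate 4, 15 without P3 WT replicate 1, 13 without WT replicate 2 and 23 without WT replicate 3. It was 0 by edgeR without the libraries rich in Gm10800, with 2 KO and 2 WT libraries left and 1777 genes at an unadjusted p under 0.05. It was 104 with the level of Gm10800 as a covariate, 83 in a fit to all 24 libraries and 300 by DESeq2's Wald test. The share of called genes that rose was 76.7% in edgeR, 64.3% by DESeq2 and 55.8% with the covariate. The authors' deposited table held 48 genes, with 36 common to both.

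Further rises in P3 were the synaptotagmin-like gene Sytl2 by 3.50, the lectin-binding gene Lgals3bp by 3.08, the lipase gene Lipc by 2.95, the lymphotoxin gene Ltb by 2.81 and Rflna by 2.59. Hoxa6 had 0 WT counts and was at least 62-fold higher. Slco5a1 fell by 1.60, Arl5a by 1.28 (from 436 ± 66.5 to 179 ± 39.7 CPM) and Gpr155 by 0.95, Tnfrsf19 went from 57.2 ± 8.4 to 20.2 ± 6.1 CPM and Cpm from 372 ± 25.9 to 186 ± 27.3 CPM. The call of each of these genes was lost in at least 4 of the 8 fits without 1 library, and those of Ltb, Rflna, Tnfrsf19 and Gpr155 in all 8. Vpreb1 (9.12 ± 3.7 and 1.12 ± 0.751 CPM, edgeR adjusted p = 0.122), Kit (7.46 ± 4.85 and 0.797 ± 0.782 CPM, 0.225), Dntt (3.37 ± 0.809 and 0.561 ± 0.49 CPM, 0.436) and Rag1 (1834 ± 290 and 1302 ± 122 CPM, 0.327) were not called.

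Distal Igh V segments were the list with the lowest camera p in P3, with 3 of 38 lower (Ighv1-75 by 2.91, Ighv1-80 by 3.03 and Ighv1-81 by 2.45, with calls kept in 1, 1 and 0 of the 8 fits without 1 library), 25 adjusted over the list alone, a median log2 fold change of -1.68 and a camera adjusted p of 8.06e-30 (adjusted p = 0.107 with an estimated correlation). Of 16 proximal Igh V segments 2 rose, Ighv5-2 by 1.98 (38.1 ± 9.47 against 9.64 ± 2.6 CPM) and Ighv5-4 by 2.09 (48.7 ± 11 against 11.4 ± 4.06 CPM), each kept in 3 of these fits, with 7 up and 1 down adjusted over the list alone (camera adjusted p = 0.000481, and adjusted p = 0.355 with an estimated correlation). All Igh V segments had 3 lower and 2 higher of 76, with 33 lower and 7 higher adjusted over the list alone (camera adjusted p = 4.34e-19, and adjusted p = 0.152 with an estimated correlation). Cell-cycle genes had 0 of 29 called and 11 lower adjusted over the list alone (median -0.78, camera adjusted p = 1.97e-11, and adjusted p = 0.113 with an estimated correlation). Interferon response genes had 0 of 17 called and 4 higher adjusted over the list alone (median 0.59, camera adjusted p = 7.45e-09, and adjusted p = 0.09 with an estimated correlation, the lowest among the 29 lists). With an estimated correlation camera thus called 0 lists in P3, against 18 with the preset one, 13 higher and 5 lower.

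Markers of other cell types and stages were higher in P3 libraries labelled KO by camera with the preset correlation. Myeloid markers had a positive log2 fold change in 13 of 13 members, with 0 called over all genes and 1 adjusted over the list alone (median 1.46, camera adjusted p = 1.45e-07). Mpo was at 222 CPM in P3 KO replicate 2 and at 3.2 to 18 CPM in the other KO libraries, beside 3.9 ± 2.34 CPM in WT. Early progenitor genes had 3 of 11 higher adjusted over the list alone (camera adjusted p = 0.000146), MHC class II and later B-cell genes 4 of 16 (0.000146), Igl segments 4 of 4 (6.41e-06), IL-7 and STAT5 signalling 2 of 17 (0.00171), and plasmacytoid dendritic cell markers 1 of 8 (0.0239). Plasma cell markers had 2 of 7 called, Prdm1 by 1.84 and Ighg2b with 3 WT counts and a ratio of 69.9 (95% interval 23.6 to 341), and Ighg2b was the 1 called of 2 Igh constant regions, while both calls were kept in 1 of the 8 fits without 1 library. Their camera adjusted p-values were 0.00205 and 0.00196, with 2 up and 1 down and with 1 up adjusted over the list alone. With immunoglobulin segments left out, which also removed Ighg2b from the list itself, plasma cell markers lost the call (0.117). For all these lists the adjusted p was 0.107 to 0.113 with an estimated correlation. Pre-B-cell receptor signalling (1 of 17 called, Igll1, and 2 adjusted over the list alone, 0.0321), adhesion genes (0 of 17 called and 1 adjusted over the list alone, 0.0339) and ribosomal protein genes (0 of 78 and 0 adjusted over the list alone, 0.0281) had adjusted p of 0.464, 0.392 and 0.737 with an estimated correlation. Without P3 WT replicate 4 ribosomal protein genes turned to the opposite direction with a camera adjusted p of 0.0801, and they lost the call without KO replicate 2 (0.522), KO replicate 4 (0.164) or WT replicate 3 (0.138). Over the alternatives with the preset correlation their value lay from 6.74e-06 to 0.522. Pre-B-cell receptor signalling lost the call without KO replicate 2 (0.0848), KO replicate 4 (0.162) or WT replicate 4 (0.31), adhesion genes without KO replicate 2 (0.13), KO replicate 4 (0.136) or WT replicate 3 (0.138), and plasmacytoid dendritic cell markers without WT replicate 3 (0.138).

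Histones and Igk J segments lay lower in P3, with 0 of 54 and 0 of 5 members called and 0 and 0 adjusted over the list alone (camera adjusted p = 1.68e-05 and 0.0446, and adjusted p = 0.464 and 0.392 with an estimated correlation). Igk J segments lost the call under DESeq2's size factors (camera adjusted p = 0.0647) and without P3 KO replicate 1 (0.168), KO replicate 3 (0.246), WT replicate 1 (0.222), WT replicate 2 (0.0977) or WT replicate 4 (0.0801). Their value was 0.113 with the level of Gm10800 as a covariate and 0.755 without the libraries rich in Gm10800. The lists below were not called by camera in P3. Igh D and J segments had an adjusted p of 0.0609, Igk V segments 0.0946, erythroid markers 0.119, Igh locus contraction genes 0.235, V(D)J recombination genes 0.334 and NK and innate lymphoid markers 0.417. Values were 0.432 for p53 targets and mitochondrially encoded genes, 0.439 for immediate early genes, 0.698 for T cell markers and 0.936 for B-lineage transcription factors. Calls were gained by Igk V segments without P3 KO replicate 2 (0.00961), KO replicate 4 (6.01e-05), WT replicate 3 (0.00772) or WT replicate 4 (0.0397), by Igh D and J segments without KO replicate 2 (0.0176) or KO replicate 4 (0.0226), by erythroid markers without KO replicate 4 (0.0188) or WT replicate 4 (0.0495) and by Igh locus contraction genes without KO replicate 4 (0.0364). Mitochondrially encoded genes gained one without KO replicate 1 (0.0345) or WT replicate 3 (0.0255), with the Gm10800 covariate (0.0197) and without the libraries rich in it (0.0037). The median and test differed in sign for mitochondrially encoded genes (median 0.08, test down) and B-lineage transcription factors (median 0.01, test down), and the median and mean for immediate early genes (0.06 and -0.12).

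Igh V segments were then compared by their position along chromosome 12, since the title of the series concerns V-to-DJ joining and since distal and proximal segments depend differently on contraction of the locus. The 45 distal segments span 114487136 to 116000461 and the 17 proximal ones 113578504 to 113879541 (mm10). The median log2 CPM of distal segments was -1.95 ± 0.237 in P1 libraries labelled KO and 0.70 ± 0.467 in WT, a difference of -2.65. In P2 it was -2.32 ± 0.298 against 2.17 ± 0.545, a difference of -4.49, and in P3 0.54 ± 0.764 against 2.58 ± 0.293, a difference of -2.03. Each had an exact permutation p of 0.0286, the smallest that 4 against 4 libraries allow, and 0.0429 after Benjamini-Hochberg adjustment over 18 tests. Every KO library lay below every WT library in these 3 comparisons. For proximal segments the difference was -0.81 in P1 (exact permutation p = 0.114), -2.42 in P2 (0.0286) and 0.02 in P3 (0.971). Without P1 KO replicate 4 the proximal difference in P1 was -1.01 (exact permutation p = 0.0286) and without P1 KO replicate 3 it was -0.3755 (0.257), and in P3 it changed sign without P3 KO replicate 2 (-0.24) and without P3 WT replicate 4 (-0.07). The distal minus proximal difference was lower in libraries labelled KO by 3.57-fold, 4.22-fold and 4.15-fold in P1, P2 and P3 (exact permutation p = 0.0286 each).

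Summed over segments, distal Igh V counts were 31.1 ± 23.6 against 78.9 ± 21.3 CPM in P1 (log2 difference -1.65, exact permutation p = 0.0571), 23.6 ± 12.5 against 334 ± 99.2 CPM in P2 (-3.95, 0.0286) and 103 ± 50.1 against 342 ± 68.2 CPM in P3 (-1.86, 0.0286). Proximal sums were 29.5 ± 16.3 against 34 ± 7.9 CPM in P1 (-0.37, 0.571), 42.8 ± 15 against 99.7 ± 28.2 CPM in P2 (-1.24, 0.0286) and 261 ± 77.2 against 99 ± 27.5 CPM in P3, higher in libraries labelled KO by 1.40 (exact permutation p = 0.0286). The sum over all Igh V segments differed by -1.41, -2.71 and -0.51 (exact permutation p = 0.0286, 0.0286 and 0.171). After adjustment over the 15 sum tests 0.0286 became 0.0536, so no summed difference passed the correction. As a reference, Igk V sums differed by 0.89, 0.02 and -0.08 (exact permutation p = 0.0857, 0.971 and 0.8), and Igl sums were 83.6 ± 50.8 against 13.1 ± 5.09 CPM in P1 (0.0286) and differed by 0.92 and 1.35 in P2 and P3 (0.0571 and 0.0286). Distal segments with at least 1 count averaged 18 of 33 in KO against 31 in WT in P1, and 22.8 of 43 against 42.8 in P2. Across segments the difference fell with distance from the D and J end, with Spearman's rho of -0.454, -0.606 and -0.649 over 66, 83 and 84 segments (permutation p = 0.00013, 1e-05 and 1e-05, the last being the smallest that 1e+05 resamples can give). Segments share reads and are not independent replicates, and how reads were divided among paralogous segments, or between strands, is not known.

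**Figure D4:**
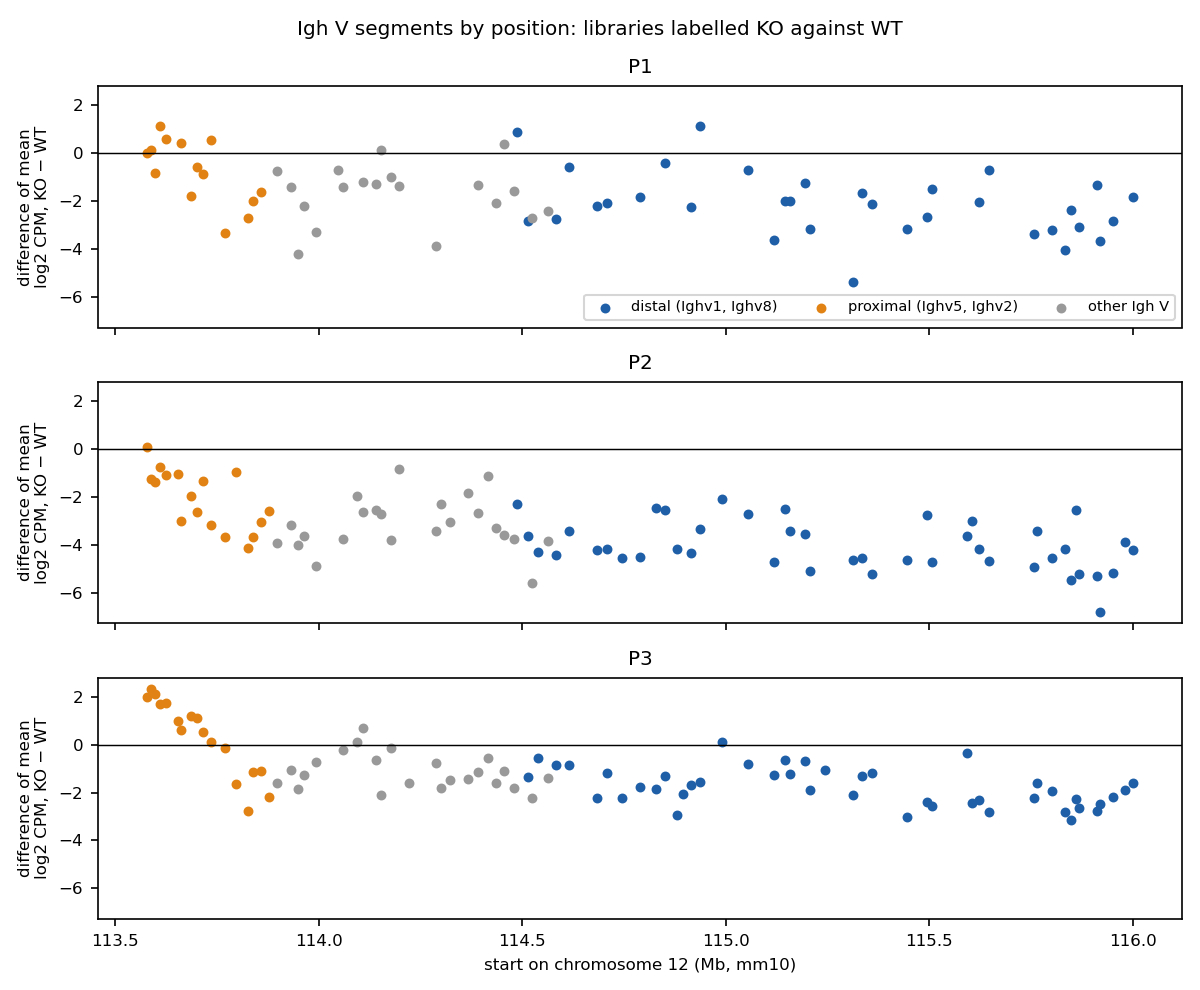
Difference of mean log2 CPM (KO minus WT) of each Igh V segment by its start on chromosome 12 (mm10), in a panel per population, with distal, proximal and other segments in separate colours. Distal segments lay lowest, with medians per library that differed by -2.65, -4.49 and -2.03.

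Whether the genotype difference itself changed between populations was tested in a joint fit of the 24 libraries. Between P2 and P1, Erg differed by 3.40 on the log2 scale (edgeR adjusted p = 4.39e-06), the surrogate light chain gene Igll1 by 3.097 (5.05e-05), Dntt by 3.83 (0.000175), Lef1 by 2.26 (5.05e-05), Vpreb1 by 3.15 (0.00136) and Myc by 2.66 (0.0485), all with a more positive effect in P2. Il2ra differed by -1.22 (0.00756), Polm by -2.13 (0.00591), Klf2 by -2.11 (0.00691) and Cd38 by -1.34 (0.0171). Between P3 and P1 Dntt differed by 5.47 (3.93e-06), Igll1 by 4.32 (4e-07), Erg by 3.87 (4e-07), Lef1 by 1.87 (0.000346) and Il2ra by -1.23 (0.00479). In all, edgeR with Benjamini-Hochberg adjustment called 138 of 16148 genes for P2 minus P1 (77 more positive and 61 more negative in P2) and 132 for P3 minus P1 (78 and 54). For P3 minus P2 it called 0, with 613 genes at an unadjusted p under 0.05. Without replicate 1, 2, 3 or 4 of every group the counts were 30, 23, 37 and 34 for P2 minus P1 and 58, 47, 66 and 63 for P3 minus P1, and P3 minus P2 gave 1 without replicate 4.

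The WT libraries gave the differences between stages in control mice. From P1 to P2, Dntt fell by 4.80 on the log2 scale (SE 0.39, edgeR adjusted p = 8.73e-06), Igll1 by 4.01, Erg fell by 3.92 (from 694 ± 142 to 45.8 ± 3.51 CPM), Myc by 3.89, Vpreb1 by 3.53 and Lef1 by 2.82. Il2ra rose by 3.27 (from 39.7 ± 3.54 to 383 ± 52.5 CPM), Polm by 3.42, the class II gene Cd74 by 1.88 and the light-chain gene Igkc by 1.60. From P2 to P3, Igll1 fell by 4.84, Dntt by 5.23, Vpreb1 by 4.59 and Erg by 1.79, and the proliferation gene Mki67 fell by 1.64 (from 2516 ± 506 to 806 ± 147 CPM). Spn, which encodes the sort marker CD43, fell by 1.64. In this fit of 16001 genes edgeR with Benjamini-Hochberg adjustment called 1683 from P1 to P2 (879 higher and 804 lower) and 180 from P2 to P3 (6 higher and 174 lower). Without P2 WT replicate 3 the counts were 1094 and 90, and without P3 WT replicate 3 the second was 99. By camera cell-cycle genes fell from P2 to P3 with 16 of 29 members lower (adjusted p = 4.07e-28, and adjusted p = 0.0248 with an estimated correlation). From P1 to P2 Igh V segments rose with 22 of 63 members higher (adjusted p = 8.93e-20, and adjusted p = 0.0543 with an estimated correlation). Myeloid markers, which B220 and CD19 sorting would remove, rose from P1 to P2 with 10 of 13 members higher (adjusted p = 3.72e-07, and adjusted p = 0.107 with an estimated correlation), and Mpo then fell by 5.08 to P3.

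Genes called in more than 1 population were compared with the number that chance would give. The cytokine receptor gene Il9r, the scaffold gene Ahnak, the RNA-binding gene Rbm24 and F5, Sytl2, Tns1, Zfhx3 and Pdzd2 rose in P1, P2 and P3 in libraries labelled KO. Tnfrsf19, the small GTPase gene Arl5a, Gm12840 and Ighv1-75 fell in all 3. P1 and P2 shared 34 genes called in the same direction of 14975 tested in both, with 2.24 given by chance and 1, Pcp4l1, called in opposite directions. P2 and P3 shared 26 of 15414 (0.322 by chance), and P1 and P3 shared 13 of 15233 (0.359 by chance). The P1 and P2 count was 19, 17, 19, 20 and 21 without P1 KO replicate 1, KO replicate 2, WT replicate 2, WT replicate 3 and WT replicate 4. The P2 and P3 count ran from 8 (without P3 KO replicate 4) to 16 (without P3 WT replicate 3) when any P3 library but WT replicate 4 was left out, and the P1 and P3 count from 3 to 7. By DESeq2's Wald test the 3 counts were 107, 141 and 65, and without the libraries rich in Gm10800 they were 5, 0 and 0.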

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

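Of the tests in this part, those of exchanged labels, of shares of P1-like cells in P2 and P3 and of summed light-chain and heavy-chain segments were chosen only after the result was seen, and the test of shares was made stricter after its first outcome. The stage score of P1, the share of P2-like cells in P1 and the test on Gm10800 were set before their results were seen.

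Values of the named genes, of the Igh V medians and of a few abundant transcripts were searched for a library far from the other 3 of its group, by its gap to the nearest of them relative to the whole range (Dixon's 95% critical value). Of 604 groups of values 49 held such a library, where chance gives about 1 in 20 groups, or about 30 here.

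In P1, KO replicate 4 lay above the other KO libraries in Cd74 (618 CPM against 272 to 315), Dntt (126 against 57.8 to 60), Ets1 (711 against 275 to 311), Ly6d (253 against 57.5 to 88.8), Hist1h2af (25.8 against 2.08 to 5.25), Hist1h2ap (90.3 against 4.16 to 15.8) and Gm42418 (7.33% of counts against 2.18% to 2.53%). P1 KO replicate 3 was high in L3mbtl1 (12.5 CPM against 1.29 to 3.12) and low in the median of proximal Igh V segments (-1.36 on the log2 scale against 0.24 to 0.54). Ifih1 was at 12.8 CPM in P1 KO replicate 2, against 12.1 to 12.2, and at 54.9 CPM in P1 WT replicate 1, against 9.21 to 15.2. P1 WT replicate 1 was also high in Rpl27a (99.9 CPM against 41.6 to 47.1), P1 WT replicate 4 in Erg (880 CPM against 572 to 612) and P1 WT replicate 3 in Kcnj15 (5.95 CPM against 0.526 to 1.12). Other values came from a single library with a few counts of a gene at 0 in the other 3. These were Rpl3l (0.769 CPM) in P1 KO replicate 3, Bok (0.087) in KO replicate 4, Ccdc33 (0.208) in KO replicate 2 and Ap3s1-ps1 (0.0991) in KO replicate 1. In P1 WT replicate 3 they were Thbs4, Slc27a3 and Gpr25 (0.0614 each), Etnk2 (0.123) and Cd177 (0.43).

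In P2, KO replicate 3 was high in the myeloid gene Itgam (362 CPM against 99.1 to 130) and low in Rag1 (1041 against 1400 to 1462). KO replicate 1 was high in mt-Ty (3.6 CPM against 1.32 to 1.41), in Gm10800 (0.575% of counts against 0.0201% to 0.0681%) and in Il33 (0.216 CPM against 0). KO replicate 2 was low in Lmo2 (14.2 CPM against 22.5 to 23.8) and high in Vpreb2 (2.32 against 0.912 to 1.11). The distal Igh V median of KO replicate 4 was -2.76, against -2.21 to -2.12. WT replicate 4 was high in Prmt2 (0.572 CPM against 0.135 to 0.202) and Vpreb2 (0.572 against 0 to 0.0674) and low in Dntt (16.3 against 20.6 to 21.4).

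In P3, KO replicate 2 was high in Mpo (222 CPM against 3.2 to 18), Car2 (40.4 against 13.4 to 17.7) and the proximal Igh V median (3.04 against 1.93 to 2.07). Car1 was high in KO replicate 1 (14.9 CPM against 5.52 to 6.72), and Ifi44 (18.5 against 8.51 to 9.29) and Rora (9.66 against 0.208 to 1.54) in KO replicate 3. WT replicate 4 was high in Gata3 (91.2 CPM against 2.86 to 2.96), Cd3d (35.7 against 11.4 to 14.8), Serpina3g (6.4 against 3.65 to 4.09) and Ly6a (0.927 against 0 to 0.152). WT replicate 3 was high in Pou2f2 (78.5 CPM against 50.2 to 54) and Lipc (5.49 against 2.32 to 2.82), WT replicate 2 in Rps4l (2.33 against 0.371 to 0.557), and WT replicate 1 in Klrk1 (4.86 against 0.0796 to 0.834) and Gm42418 (3.85% of counts against 1.08% to 1.48%).

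Named genes were searched for called differences of the genotype effect in the joint edgeR fit. For P2 minus P1 there were 23. The effect was more positive in P2 for Erg (3.40), Lef1 (2.26), Igll1 (3.097), Dntt (3.83), Vpreb1 (3.15), Ifi44 (3.005), Heyl (3.34), Ccnd2 (1.49), Itga4 (0.71), Scn4b (4.51) and Myc (2.66). It was more negative in P2 for Socs1 (-5.81), Polm (-2.13), Klf2 (-2.11), Il2ra (-1.22), Cd38 (-1.34), Thbs4 (-5.40), Igkv1-135 (-2.26), Ren1 (-5.00), Iglv3 (-2.50), H2-Aa (-1.89), Top2a (-0.97) and Ighv10-3 (-3.74). For P3 minus P1 there were 29. The effect was more positive in P3 for Erg (3.87), Igll1 (4.32), Dntt (5.47), Vpreb1 (3.97), Lef1 (1.87), Ccnd2 (2.31), Lgals3bp (3.74), Scn4b (6.64), Dlx1 (5.98), Mmrn1 (8.55), Hoxa6 (7.46), Ighv1-58 (8.39), Kit (5.199), Ighg2b (5.65), Myc (3.12), Zfp365 (10.8), Tnfrsf19 (1.88), Ifi44 (2.53), Itga4 (0.71) and Ighv1-74 (5.62). It was more negative for Klf2 (-2.21), Polm (-2.16), Socs1 (-5.18), Cd38 (-1.55), Il2ra (-1.23), Igkv1-135 (-2.63), Ren1 (-5.64), Gpr155 (-1.25) and Pmepa1 (-8.24). Ighv1-58, Ighv1-74, Pmepa1 and Hoxa6 had 0 counts in a group, and Socs1, Thbs4 and Ighg2b had 1 to 3. Mmrn1 and Zfp365 were not tested in P3 alone. The differences of these genes are no bounds.

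The first pattern weighed was the higher Erg in P2 and P3 libraries labelled KO. An exchange of labels in P2 and P3 but not in P1 would turn the genes shared with P1 around, and 2.78% of them (1 of 36) went in opposite directions, which argues against it, while an exchange in every population would escape this test. P1-like cells carry more Erg, but the gates on CD25 (P2 and P3) and CD43 (P3) would remove them. P2 libraries labelled KO did not score toward WT P1 (exact permutation p = 0.657). Shares were not taken from genes lower in P1, which such cells would dilute. Genes higher in P1 cannot decide on such cells, as the quartiles of their shares spanned that of Erg. In P2 Erg implied 66.3% and these genes a median of 49.6% (24.4% to 76.9%, and 15.4% in WT libraries held out), and in P3 Erg implied 25.9% and they 19.7% (4.65% to 41.1%, and 7.97%). Reads from a deleted allele may also be counted, which values summed over the gene cannot show, and a direct effect of the genotype on Erg transcription stays open and untested.

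The second pattern was the fall of Igh V segments. Lower depth or detection would lower Igk V segments as well, but their sum changed by 0.01739 on the log2 scale in P2 and by 0.89 in P1 (exact permutation p = 0.971 and 0.0857) and showed no fall like that of Igh V segments, which argues against it there. Reads moving between similar segments would leave the sum over all Igh V segments level. In P2 and P1 it changed by -2.713 and -1.41 with no library overlap, which argues against such moves as the whole cause. In P3 it changed by -0.5134 with overlap, so moves between families stay open. The distal sum changed by -1.86 and the proximal by 1.40 without overlap, which argues against moves within families there. A lower rate of distal joining in the libraries labelled KO is a candidate explanation in P1 and P2, as a hypothesis, while fewer cells with a joined heavy chain, or less transcription of unjoined segments, may give the same fall, and counts of V-to-DJ joints in genomic DNA, which were not available, would tell these apart.

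The third pattern was a shift of P1 libraries labelled KO toward P2, seen in Il2ra, Dntt, Lef1 and Cd74 but not in Igh V segments, which rose from WT P1 to P2 and fell in P1 KO, nor as a call in Erg or Igll1, which fell from WT P1 to P2. On the WT axis from P1 to P2 they scored 0.617 ± 0.089 against 0.267 ± 0.0806 (SD, n = 4, exact permutation p = 0.0286), above WT in 4 of 4 libraries, although the adjusted p over 3 scores was 0.0858 and fails the correction. Without the KO libraries rich in Gm10800 the lowest KO score still exceeded the highest WT score by 0.248, more than the SD of the WT scores, which argues against these libraries as the cause. P2-like cells, which the CD25 gate of P1 would remove, imply 1 share. Genes lower in WT P2 implied 78.1% (quartiles 51.6% to 92.5%) and those higher 33.7% (19.3% to 55.7%). Ranges overlap, so this cannot decide on such cells. An earlier start of the P2 programme also stays open and untested.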

How the results depend on the processing

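The alternatives on the level of Gm10800, the limma fit to the authors' log2 CPM, the size factors for lists and differences, the leave-one-out fits of WT stages and overlaps and the other fits behind overlaps were chosen after seeing the data. Alternatives meant for normalised values (pseudocount, filter on low values, scaling) were not run, since the tables held counts, and limma without trend and robust was run as edgeR without robust fitting. All called genes of P1, P2 and P3 that had a value in an alternative fit kept their direction there. Of the values of named called genes under the alternatives, 744 of 932 in P1, 749 of 916 in P2 and 242 of 440 in P3 stayed past the threshold in the same direction, and 188, 167 and 198 lost the call. For called lists 128 of 149, 193 of 246 and 207 of 246 kept it, and 1 value in P3 reversed.

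DESeq2's Wald test called more genes, 868 in P1 (401 higher, 467 lower), 721 in P2 (324 and 397) and 300 in P3 (193 and 107), and all genes called in the main comparisons were among them. A fit to all 24 libraries called 715 in P1 (365 and 350) and 83 in P3 (61 and 22). Without the expression filter 5 genes were lower in P3, voom with weights per library gave 16 lower in P3, and limma on the authors' log2 CPM gave 51 higher in P3. The cause was not tested. Counts under DESeq2's size factors, edgeR without robust fitting, a minimum log2 fold change and the authors' own comparison stayed within 1.5 times the main ones.

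With the level of Gm10800 as a covariate 139 genes were called in P1 (79 and 60), 433 in P2 (167 and 266) and 104 in P3 (58 and 46), and the cause was not tested. Without libraries over 0.3% on Gm10800 the counts were 80 in P1 (41 and 39), 97 in P2 (35 and 62) and 0 in P3 (0 and 0) by edgeR, with 1777 genes at an unadjusted p under 0.05 in P3, and 2 lists were higher in P2. Fewer libraries were left in these fits.

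With an estimated correlation camera called 2 lists in P1 (0 higher, 2 lower), 3 in P2 (0 and 3) and 0 in P3 (0 and 0), so the list calls rest mostly on the preset correlation. Gene families that turned to the opposite direction were mitochondrially encoded genes in P1 without KO replicate 4 (adjusted p = 0.0125, leave-one-out range 0.0125 to 0.956, and down to 0.000338 over all alternatives), replication-dependent histones in P1 without KO replicate 4 (0.000201, range 0.000201 to 0.867, and down to 3.6e-06) and cytosolic ribosomal proteins in P3 without WT replicate 4 (0.0801, range 6.74e-06 to 0.522). These 2 lower values came from fits without libraries over 0.3% on Gm10800, in the direction of the main test. The cause was not tested.

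Summed in place of medians, Igh V segments gave a distal change of -1.65 in P1 (exact permutation p = 0.0571) and a change over all segments of -0.51 in P3 (0.171), both no longer past the threshold, and a proximal rise of 1.40 in P3 (0.0286), under the threshold before adjustment but at 0.0536 after it over the 15 sum tests. Sums follow the abundant segments and medians weight all alike. Distal medians stayed past the threshold in all leave-one-out fits.

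The overlaps of P1 with P2, P2 with P3 and P1 with P3 were 76, 46 and 26 at an adjusted p of 0.1, 8, 6 and 2 at 0.01, and 107, 141 and 65 by DESeq2's Wald test. Without libraries over 0.3% on Gm10800 they were 5, 0 and 0, and fewer libraries were left.

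Leave-one-out fits, which had fewer samples, called 131 to 251 genes in P1 (60 to 102 higher, 71 to 161 lower), 138 to 232 in P2 (58 to 94 and 80 to 149) and 9 to 30 in P3 (9 to 25 and 0 to 5). Lists called numbered 10 to 12 in P1 (6 to 8 higher, 4 to 6 lower), 11 to 17 in P2 (1 to 6 and 9 to 11) and 17 to 19 in P3 (10 to 13 and 4 to 8, the 8 without P3 KO replicate 4). Of the named called genes 30 of 47 in P1, 26 of 46 in P2 and 4 of 22 in P3 were called in all 8 fits. Igh V medians changed by -2.40 to -1.95 in P1 over all segments, -2.80 to -2.51 for distal and -1.01 to -0.3755 for proximal ones. In P2 they changed by -4.045 to -3.76, -4.68 to -4.33 and -2.56 to -2.27, and in P3 by -1.57 to -1.085, -2.28 to -1.73 and -0.24 to 0.13. Over all segments in P3 the exact permutation p rose to 0.0857 without any 1 of the WT libraries. Differences between populations numbered 23 to 37 for P2 minus P1, 0 to 1 for P3 minus P2 and 47 to 66 for P3 minus P1. WT stages gave 1094 to 1838 and 90 to 216 genes, and overlaps 17 to 35, 8 to 26 and 3 to 12.

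The replicate block tested whether replicate numbers pair the libraries. After removal of group means, KO and WT libraries of 1 number correlated from -0.318 to 0.169 over 12 pairs, and in 1 pair the own number was the closest partner, so the numbers did not pair genotypes. Libraries of 1 genotype and number in different populations correlated from -0.178 to 0.387 over 24 pairs, with the own number closest in 9. With the block 150 genes were called in P1 (71 and 79), 129 in P2 (45 and 84) and 0 in P3 (0 and 0) by edgeR, with 947 genes at an unadjusted p under 0.05 in P3, and overlaps were 15, 0 and 0. The block uses up degrees of freedom. Paired sign flips of Igh V medians cannot give a p below 0.125, which each of these changes reached: -2.15 and -2.65 in P1 (all and distal), -3.895, -4.49 and -2.415 in P2 (all, distal and proximal) and -1.345 and -2.03 in P3 (all and distal).

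Depth and replicate number limit what was seen. For well-expressed genes in simulated counts the test recovered 9%, 24% and 16% of 2-fold changes and 69%, 83% and 75% of 4-fold changes in P1, P2 and P3, so a gene not called was not shown to be level.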

Other observations

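The counts over other splits of the libraries and the values of genes outside the naming rule in this part were chosen only after the results were seen, and the stage scores of P2 and P3 were set before theirs.

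Each count of called genes or lists was set against other splits of the same libraries into groups of the same sizes. The gene counts of 290, 273 and 43 in P1, P2 and P3 were reached by 1 of 35 splits, the real one, with highest other counts of 1, 7 and 2. This is the smallest share 35 splits allow, and the others mix genotypes, so it does not exclude chance. Lists called by camera with the preset correlation gave the same in P2 (18, highest other 12) and P3 (18, highest other 14). In P1, 4 of 35 splits, the real one included, called as many lists as the real 11, and the highest other called 13. The WT counts of 1683 and 180 were likewise reached by 1 of 35 splits, with a highest other of 0.

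For differences of the genotype effect splits cannot exclude chance, as they mix genotypes and undo the effect itself. Of 100 splits 2 reached the real 138 for P2 minus P1, and 1 reached the real 132 for P3 minus P1 (highest other 108). For P3 minus P2 all 100 splits reached the real 0, and the highest other was 5. The other split of P2 minus P1 called 563 genes, which points to a structure of the samples. It set all 4 WT libraries against all 4 KO libraries in P1 with the groups exchanged, and kept the real groups in P2, so that the P1 effect was added rather than subtracted. The next highest count was 41. A genotype effect of the same direction in P1 and P2 gives a larger difference in that split than in the real one, which is a property of the groups and not of chance.

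The overlaps of 34, 26 and 13 genes were compared with other splits by taking from each split as many genes of smallest p as the real one called, so that other splits had as many genes to share. Of 100 splits 2 shared as many as the real 34 for P1 and P2. For P2 and P3 and for P1 and P3 only the real one did, with highest others of 8 and 5. Chance is unlikely here but not excluded. The other split of P1 and P2 shared 36 genes, and the next highest shared 15. It set both P1 libraries and all 3 P2 libraries with over 0.3% of counts on Gm10800 on 1 side, together with libraries low in Gm10800, and what these sides have in common was not tested. Without these libraries P1 and P2 shared 5 called genes, with fewer libraries left.

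P2 libraries labelled KO scored 0.221 ± 0.0356 on the WT axis toward P1 and WT libraries 0.228 ± 0.0188 (SD, n = 4, exact permutation p = 0.657), and their mean was not above that of WT, which argues against a general shift of P2 toward P1 even though Erg, Igll1 and Vpreb1 were higher there. P3 libraries labelled KO scored 0.58 ± 0.129 toward P2 and WT libraries 0.468 ± 0.14 (SD, n = 4, exact permutation p = 0.314), and with a higher mean and overlapping libraries a shift was neither shown nor excluded. The bound set beforehand against a shift, a p of 0.05 or more, was wrong by itself, since such a p with 4 against 4 libraries does not show that scores did not differ.

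Kcnj15 lies 58.9 kb from Erg on mm10 chromosome 16 (95257558 to 95300260). Its log2 fold change in libraries labelled KO was 5.76 in P1, 6.53 in P2 and 3.85 in P3, with edgeR adjusted p-values of 0.00544, 0.00464 and 0.0963, and every KO library lay above every WT library in each population. Ets2, 115 kb from Erg on the other side, changed by -0.89, -0.60 and 0.14, and was not called, nor were Gm7976 at 292 kb and Psmg1 at 393 kb. Whether reads run on from one gene into another was not tested, since no values per exon or strand were available.

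Genes of the Hoxa cluster were looked at without a set test. In P2 edgeR called 3 of 5 tested, Hoxa3 by 2.34, Hoxa6 by 3.28 and Hoxa7 by 2.21, and in P3 it called 2 of 6, Hoxa7 by 2.48 and Hoxa6, which had 0 WT counts. In P1 it called 0 of 5, and Hoxa3 in P1 (-0.27) and Hoxa11 in P3 (-0.27) were negative. Of the Hoxb, Hoxc and Hoxd genes, 3, 2 and 1 were tested in each population and 0 were called. Csf2rb, the common beta chain of the IL-3 and GM-CSF receptors, rose by 2.11 in P2 (edgeR adjusted p = 0.00425) and by 2.35 in P3 (0.00747), and by 0.95 in P1 (0.155). The effect on Csf2rb was not called as different between populations in the joint fit (adjusted p = 0.155 for P2 minus P1 and 0.077 for P3 minus P1).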
